A study of Mus musculus with 6 samples.

How the data were processed

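Total RNA of whole lungs was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, in 6 mice-derived samples at postnatal day 15: 3 labelled as controls and 3 labelled Foxa2-/-. The deposited values are on a log2 scale and, per the submitters' processing notes, were made with RMA, which corrects background, brings the arrays to a common distribution and summarises the probes of each probe set. The version and settings of RMA are not given in the sources used here. The log2 scale was read from the values themselves, which run from 2.36 to 14.88 with array medians of 7.85 to 7.91. Sorted values of the 6 arrays differed by at most 0.164 at any rank, so the arrays had been equalised before deposit, and the values were not centred gene by gene. Because RMA equalises the arrays, a shift of most genes in one direction would not be seen, and differences near the floor or the top of the scale can be compressed. The scanner files were not used here.

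Groups were taken from the genotype label of each sample. The strain label names the same SPC(+)Cre(-) genotype in both groups and conflicts with the genotype label of the null samples, so Foxa2 was read first in every sample. Samples are named by group and replicate, and replicate numbers, given in accession order, pair nothing. The labels call the animals littermates but do not say that each array is a separate animal, so p-values measure the spread between these samples, which may be partly technical. No pair of arrays held identical values throughout. The first number in the sample titles, whose meaning is not given, is shared by control replicate 2 and null replicates 2 and 3, and was treated as a possible batch.

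Of 45101 probe sets, 64 Affymetrix control probe sets were left out and 45037 were tested, with no filter on dim signal. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 are unnamed here, and no gene was named from a probe set with several. For 34754 of the 34945, the Entrez identifier was found in the RefSeq gene table of assembly GRCm38.p6, used for names only; 0 symbols needed an update. Each of 18193 genes was represented by its single-gene probe set with the highest mean over all 6 arrays, and disagreeing probe sets of a named gene are given. No genome build goes with the array values, and no coordinates are printed.

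The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, null minus control, no covariate). Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold and 95% intervals. Probe sets and genes were adjusted separately. Before the data were examined, 31 gene lists (cell types of the lung, neighbouring tissues, pathways and tissue handling) were fixed. Of their 602 entries 558 had a gene on the array, 2 of these through a synonym, for 540 different genes, of which 18 are in more than 1 list. Each list was tested with camera at an inter-gene correlation of 0.01 and adjusted over the 31 lists, and members were counted over all genes and adjusted over the list alone. Alternatives used an estimated correlation and fry. The genes named were fixed by a rule: Foxa2; the 10 largest rises and 10 largest falls among genes that passed and whose groups do not overlap, leaving out unnamed predicted and sex-linked genes; and from each list up to 4 members that passed, or where none did up to 2 with the smallest p. Other list members that are given with values outside that rule were chosen after their values were seen: Ccl8, Ccl11, Il4, Il13, Il33, Agr2, Muc5ac, Muc5b, Spdef, Clca1, Arg1, Rnase2a, Chil4, Alox5ap, Alox15, Lcn2, Saa3, Cldn10, Cyp2f2, Scgb1a1, Sftpc, Rag1, Jchain and Ldha, and Foxa3 where it is given as a goblet cell gene.

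Alternatives, set before the data were examined, were: median centring and cyclic loess between arrays; only probe sets brighter than the median or the 25th percentile of means; eBayes with trend and robust settings; array weights; the title number as a fixed block, as a random block (duplicateCorrelation, statmod 1.5.0) and as a restriction to the 3 samples that share it; each sample left out in turn; the mean of a gene's probe sets; an adjusted p under 0.1; and a minimum of 2-fold. On data simulated for the comparison of null with control over 18193 genes, the gene test recovered 59.7% of 67 genes changed by 1 log2 unit, 89.6% of 67 changed by 2 and 92.4% of 66 changed by 3, and called 9 unchanged genes. Among 200 simulated unshifted lists 1 passed the list test at 0.05, and the simulated list shifted by 1 log2 unit passed it too. The simulated genes were drawn independently, so these counts do not show how the list test behaves where members of a list move together. Estimated correlations within the real lists reached 0.847.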

Results

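Whole-lung RNA from mice at postnatal day 15 was measured on 6 Affymetrix whole-genome mouse arrays, 3 from control animals and 3 from littermates whose genotype label reads Foxa2-/-. Foxa2 is a forkhead transcription factor of the lung epithelium. The design text asks how its loss bears on type 2 (Th2) inflammation and on an excess of mucus-making goblet cells. The strain label of all 6 samples reads SPC(+)Cre(-) and places doxycycline (Dox) from embryonic day 6.5 to 12.5. The array medians lay between 7.85 and 7.91 on the log2 scale, and the number of arrays, 3 per group, limits the precision of every value. Over all probe sets, Pearson's r between pairs of arrays, which is across probe sets and not across samples, ran from 0.972 to 0.992. The first principal component held 38.6% of the variance and separated the groups, with scores of -30.6 to -24.7 in controls and 21.5 to 35.5 in null lungs. The next one, with 31.2%, set null replicate 1 (50.8) apart from null replicates 2 and 3 (-26.2 and -23.1). Null replicates 2 and 3 and control replicate 2 share the first number in the sample titles, and the other 3 samples each have their own. Pairwise r did not always follow genotype. It was highest for null replicates 2 and 3 (0.9921) and for control replicates 1 and 2 (0.9914). Null replicate 1 was nearer to control replicate 1 (0.9783) than to null replicates 2 and 3 (0.9762 and 0.9772). Control replicate 2 was as near to null replicate 3 (0.9876) as to control replicate 3 (0.9871). The 3-prime minus 5-prime difference of the Gapdh control probe sets, a measure of RNA integrity, was 1.06 to 1.23 log2 units in controls and 0.91 to 0.97 in null lungs. That of Actb was 0.46 to 0.65 in controls and 0.43 to 0.47 in null lungs. For Gapdh every null array lies below every control, and for Actb the groups overlap, so the Gapdh difference stands beside every group comparison that follows. Of 64 Affymetrix control probe sets, 10 had every null array above all controls and 0 had every one below, and 0 had an adjusted p under 0.05.

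Foxa2 signal was low in every lung labelled Foxa2-/-. Its only probe set averaged 10.37 ± 0.16 in controls and 6.07 ± 1.43 in null lungs (log2, SD, n = 3 each), a ratio of 19.7-fold. The 3 null lungs read 7.72, 5.38 and 5.13, against 10.28, 10.56 and 10.28 in controls, so replicate 1 kept the most signal. The difference of -4.30 (SE 0.66, 95% interval -5.88 to -2.72) had a limma adjusted p of 0.0599 and therefore did not pass the 0.05 threshold. Without null replicate 1 the difference was -5.12 (SE 0.14) with an adjusted p of 0.00227, and leaving out any other array gave adjusted p values between 0.15 and 0.214. Among the 3 samples that share a title number, of which 1 is a control, it was -5.31. Foxa2 passed with that number as a random block (-4.64, limma adjusted p = 0.0177), array weights (-4.94, 0.00535) and trend and robust settings (-4.30, 0.044). It did not pass with median centring (adjusted p = 0.053) or cyclic loess (0.0653). The genotype label follows the signal in all 6 samples, while the strain label reads SPC(+)Cre(-) in both groups. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here.

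In the null lungs 104 of 18193 genes changed, 86 upward and 18 downward. The largest rise among named genes that passed was in Slc26a4, which encodes the anion exchanger pendrin. It went from 7.00 ± 0.92 to 12.60 ± 0.77 (log2, SD, n = 3 each), 48.2-fold (log2 change 5.59, SE 0.55, adjusted p = 0.0222). Fxyd4, a regulator of the sodium pump, rose by 4.48 (SE 0.46), and Dntt, the template-free DNA polymerase of developing lymphocytes, by 4.08 (SE 0.56). Ccl24, an eosinophil-attracting chemokine, rose by 3.63 (SE 0.48), Prg2, the major basic protein of eosinophil granules, by 3.50 (SE 0.26), and Mmp12, the macrophage elastase, by 3.40 (SE 0.48). The remaining genes among the 10 largest rises that passed were Fetub (3.45, SE 0.30), Prmt8 (3.43, SE 0.35), Tnfrsf9 (3.39, SE 0.31) and Lemd1 (3.27, SE 0.21), of which Tnfrsf9 is a costimulatory receptor of activated T cells. Control means of Fetub, Prmt8 and Lemd1 (4.98, 4.96 and 4.37) lie below the 25th percentile of every array, so the size of their changes is uncertain.

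Among genes that passed, the deepest fall was in Pgc, the precursor of an aspartic protease made in stomach and in alveolar type II cells. It went from 10.61 ± 0.58 to 6.37 ± 0.69 (log2, SD, n = 3 each), 18.9-fold lower (log2 change -4.24, SE 0.42, adjusted p = 0.0222). Bex2 fell by 3.59 (SE 0.28) and Elapor1 by 1.65 (SE 0.12). Atp7b, a copper transporter, fell by 1.95 (SE 0.28), and Apela, a secreted peptide, by 1.96 (SE 0.23). Cth, an enzyme of cysteine synthesis, fell by 1.37 (SE 0.18) and Gsta3, a glutathione transferase, by 1.20 (SE 0.17). Slc35d3 (-1.56, SE 0.13), Slc17a2 (-1.55, SE 0.21) and Myo16 (-1.41, SE 0.17) complete the 10 largest falls among genes with a full name. Null means of Slc35d3, Apela and Myo16 (4.63, 5.54 and 5.68) are dim in the same sense. Adjusted p values of these 20 genes ran from 0.0152 for Prg2, Lemd1 and Elapor1 to 0.0499 for Mmp12, Atp7b and Gsta3. Probe sets of Atp7b and of Apela disagree: the 2 dimmer ones of Atp7b gave -0.41 and -0.30, and the other one of Apela gave -0.03. With the mean of a gene's probe sets Atp7b was -0.89 (adjusted p = 0.117) and Apela -0.99 (adjusted p = 0.0502), and Tnfrsf9 was 1.86 (adjusted p = 0.0315).

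**Figure D1:**
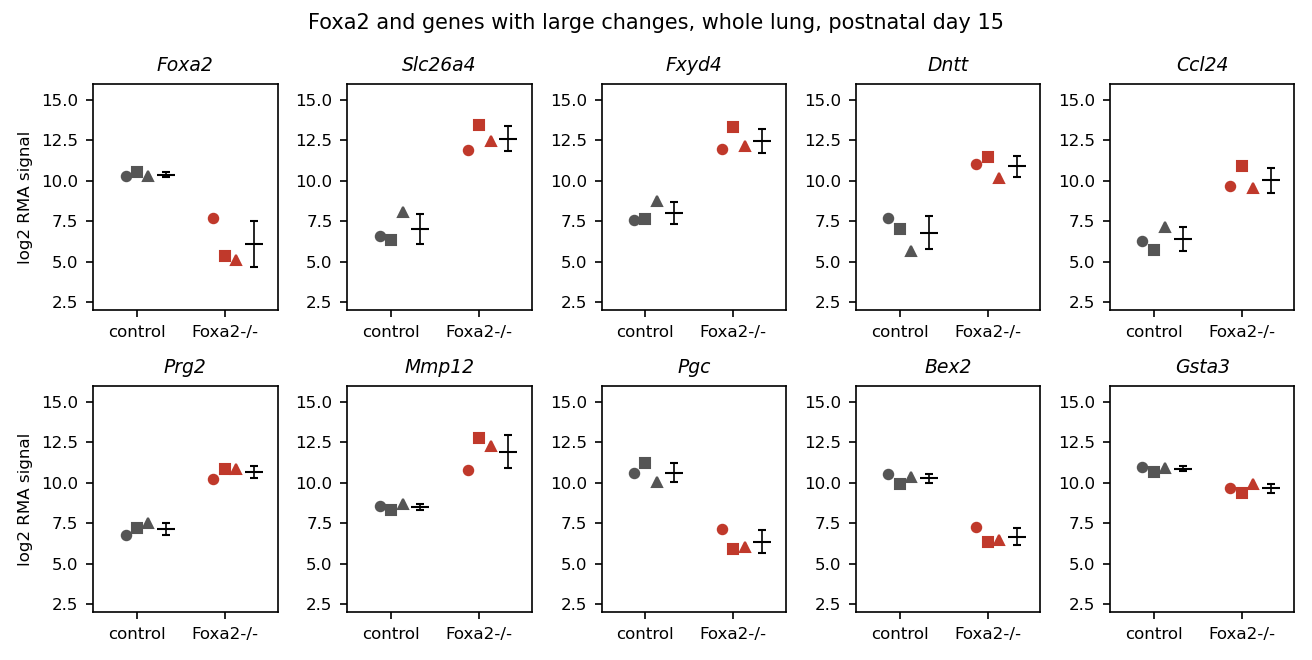
Log2 RMA signal of Foxa2 and 9 genes that changed, in control and Foxa2-/- whole lungs at postnatal day 15. Each point is an array (circle, square and triangle for replicates 1, 2 and 3), with the group mean and SD (n = 3) beside it; Foxa2 read 5.13 to 7.72 in null lungs against 10.28 to 10.56 in controls, while Slc26a4 read 11.90 to 13.42 against 6.37 to 8.06.

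All 104 genes had every null array beyond all 3 controls, and their log2 changes were at least 0.79 in size with a median of 1.52. Over all genes, 1972 lay above and 1588 below every control, 19.57% where chance gives 10%. At the level of probe sets, limma called 45 of 45037, 36 higher and 9 lower. These counts depend on single arrays. No gene passed without control replicate 1, control replicate 2 or null replicate 3, although 1654, 1801 and 2111 then had an unadjusted p under 0.05, beside 2246 with all arrays. Without control replicate 3 limma called 19 genes (17 of them among the 104), without null replicate 2 it called 7 (6 of them), and without null replicate 1 it called 249 (85 of them). For probe sets, the calls numbered 144 without null replicate 1, 3 without null replicate 2, and 0 without any other array (3477 to 4489 at an unadjusted p under 0.05). With the title number as a block, which leaves the 3 samples that share it, no gene passed (2121 at an unadjusted p under 0.05). That fit rests on 1 control array and 2 null arrays. With the title number as a random block, which keeps all arrays, limma called 399 genes (287 higher, 112 lower) and 279 probe sets. The correlation used there comes only from the 3 samples that share a number. It cannot be told apart from null replicate 1 standing apart from null replicates 2 and 3.

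Of 31 gene lists fixed before the data were examined, 24 shifted against all other genes, 19 upward and 5 downward (limma's camera with a preset inter-gene correlation of 0.01). None passed with an estimated correlation, whose adjusted p is given for each list. With fry, which tests whether a list moves one way on balance, 7 passed. For some of the 24 lists, not every null array's median lay beyond all controls in the list's direction. These were the Th1, type I interferon, ciliated, alveolar type I, mast cell, neutrophil, T cell, B cell, endothelial and heart lists. The 3 samples that share a title number are 1 control and 2 null arrays, so 1 control array carries each difference among them and no list test is given there. The value given as "within the shared number" is both that within-batch median and the value with the title number as a block.

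Cytokines, receptors and chemokines of the type 2 response shifted upward as a list, with a median of 0.91 (camera adjusted p = 2.62e-06; adjusted p = 0.311 with an estimated correlation; fry adjusted p = 0.072). Of the 25 members measured, 2 rose, none fell and 23 did not pass over all genes. Adjusted over the list alone, 11 rose. A positive change was seen in 20 of the 25, and in every null array 11 lay above all controls and 1 below. Ccl24 rose 12.4-fold, as given above, and Ccl17, a chemokine that attracts type 2 T cells, rose 5.41-fold, from 9.59 ± 0.44 to 12.03 ± 0.42 (log2, SD, n = 3 each; log2 change 2.44, adjusted p = 0.036). Members that did not pass over all genes include the chemokines Ccl8 (4.15, SE 0.62, adjusted p = 0.0568) and Ccl11 (2.75, SE 0.82, adjusted p = 0.236), and the cytokines Il4 (1.43, SE 0.39, adjusted p = 0.2), Il13 (1.27, SE 0.38, adjusted p = 0.234) and Il33 (1.05, SE 0.22, adjusted p = 0.116). The list median was 1.09 within the shared number, 0.35 without null replicate 2, 0.31 over genes brighter than the median and 1.88 over those above the 25th percentile, and 7 of the 25 members also stand in another list.

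Genes of goblet cells and mucus shifted upward as a list, with a median of 0.94 (camera adjusted p = 1.76e-06; adjusted p = 0.328 with an estimated correlation; fry adjusted p = 0.0938). Of 24 measured members 1 rose (Slc26a4, given above), none fell and 23 did not pass over all genes, while 12 rose and 1 fell when adjusted over the list alone. Agr2, which folds mucins, had a log2 difference of 2.16 (SE 0.38, adjusted p = 0.0795), and Foxa3, a forkhead factor related to Foxa2, one of 1.25 (SE 0.27, adjusted p = 0.123). Muc5ac and Muc5b, the gel-forming airway mucins, differed by 1.12 (SE 0.56, adjusted p = 0.487) and 1.10 (SE 0.72, adjusted p = 0.602). Spdef, a driver of goblet cell differentiation, read 6.90 ± 0.15 in controls and 6.87 ± 0.22 in null lungs (log2, SD, n = 3 each). Clca1 averaged 13.38 ± 0.22 in null lungs, but controls spread from 7.08 to 11.61, so its brightest probe set did not pass (3.50, SE 1.11, adjusted p = 0.274); its dimmer probe set did, at the level of probe sets (3.10, SE 0.25, adjusted p = 0.0292). Within the shared number the list median was 1.52, and without control replicate 2, the control with the lowest mucus genes, it was 0.58.

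**Figure D2:**
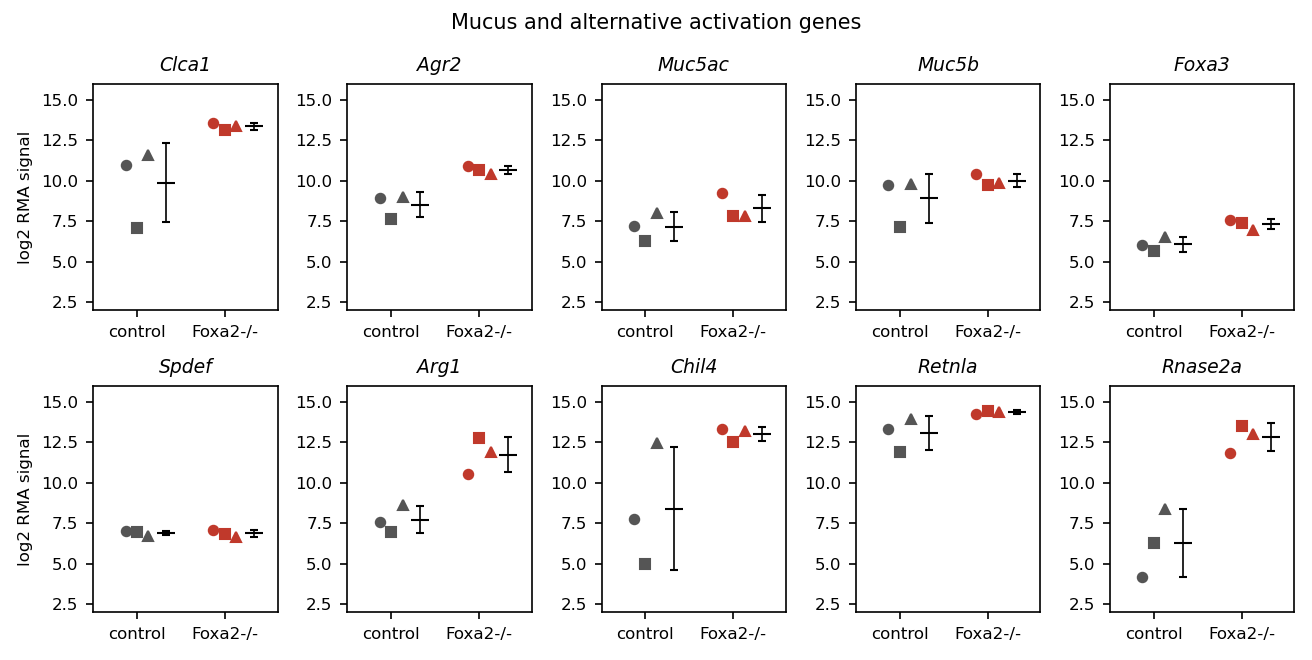
Log2 RMA signal of 10 genes of mucus production and alternative activation in control and Foxa2-/- lungs, drawn by array (circle, square and triangle for replicates 1, 2 and 3) with group mean and SD (n = 3). Controls differ widely in Clca1 (7.08 to 11.61) and Chil4 (up to 12.47), null lungs sit between 13.15 and 13.58 in Clca1, and Spdef is near 6.9 in both groups; none of the 10 passed over all genes.

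Genes of alternatively activated macrophages, the state that type 2 cytokines induce, shifted upward as a list. Their median was 1.39 (camera adjusted p = 4.51e-10; adjusted p = 0.279 with an estimated correlation; fry adjusted p = 0.0487) and 1.56 within the shared number. Of 19 members, 2 rose over all genes (Ccl24 and Mmp12), none fell, and 14 rose when adjusted over the list alone. Mmp12 went from 8.52 ± 0.20 to 11.92 ± 1.03 (log2, SD, n = 3 each), 10.5-fold. Arg1, which breaks down arginine, differed by 4.01 (SE 0.63, adjusted p = 0.0605), and Rnase2a, an eosinophil-type ribonuclease listed under an older name, by 6.52 (SE 1.04, adjusted p = 0.0618). Chil4, a chitinase-like protein, differed by 4.60 (SE 1.72, adjusted p = 0.35) and read 12.47 in control replicate 3 against 7.75 in control replicate 1, with control replicate 2 lower still.

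Alveolar macrophage genes shifted upward as well, with a median of 0.58 (camera adjusted p = 1.54e-08; adjusted p = 0.189 with an estimated correlation; fry adjusted p = 0.0158) and of 0.67 within the shared number. Of 20 members 3 rose over all genes and 10 when adjusted over the list alone. Itgax, an integrin of alveolar macrophages and dendritic cells, went from 9.76 ± 0.39 to 11.70 ± 0.26 (log2, SD, n = 3 each), a rise of 1.94 (SE 0.23, adjusted p = 0.036). Trem2, a lipid-sensing receptor, rose by 1.64 (SE 0.15, adjusted p = 0.0198) and Cd68, a lysosomal protein, by 1.45 (SE 0.13, adjusted p = 0.0198). With the mean of its probe sets Trem2 was 0.95 (adjusted p = 0.0315). Genes of monocytes and interstitial macrophages shifted upward with a median of 0.87 (camera adjusted p = 3.16e-06; adjusted p = 0.325 with an estimated correlation) and of 1.11 within the shared number. None of their 16 members passed over all genes, and 7 rose when adjusted over the list alone; C1qa, a complement subunit, differed by 1.03 (SE 0.18, adjusted p = 0.0795). In the list of dendritic cells and antigen presentation 1 of 22 members, Ccl17, rose over all genes and 6 when adjusted over the list alone. Its median was 0.79 (camera adjusted p = 1.54e-08; adjusted p = 0.317 with an estimated correlation), 0.48 within the shared number and 0.47 without control replicate 3.

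Eosinophil genes had the highest median of the 3 granulocyte lists, 1.58 (camera adjusted p = 1.26e-08; adjusted p = 0.279 with an estimated correlation; fry adjusted p = 0.0379), with 1.70 within the shared number. Of 9 members 3 rose over all genes and 6 when adjusted over the list alone, and all 9 had a positive change. Prg2 went from 7.16 ± 0.39 to 10.66 ± 0.36 (log2, SD, n = 3 each), 11.3-fold. Epx, the eosinophil peroxidase (adjusted p = 0.0208), and Prg3, another granule protein (adjusted p = 0.0429), also rose, from control means of 5.47 and 4.85. Those lie below the 25th percentile of every array (5.69 to 5.78), where the deposited values do not show whether signal is above background, so no fold is given. Of the 9 eosinophil genes 4 also stand in another list. Mcpt2, a mast cell protease, rose from a mean of 4.22, equally dim, to 5.74 (adjusted p = 0.0499), the only one of 15 mast cell and basophil genes to pass, both over all genes and adjusted over the list alone. That list had a median of 0.13 (camera adjusted p = 0.0243; adjusted p = 0.383 with an estimated correlation) and of 0.62 within the shared number. Its call ended without control replicate 2 (0.11, adjusted p = 0.0991), without null replicate 3 (0.19, adjusted p = 0.225), over genes above the 25th percentile (0.09) and over genes brighter than the median, where the median was -0.23. It was 0.21 to 0.27 without each of the other arrays, and 0.34 to 0.35 with the title number as a random block and with array weights.

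None of 13 neutrophil genes passed over all genes or adjusted over the list alone. Prtn3, a granule protease, differed by 1.51 (SE 0.42, adjusted p = 0.207) and Mmp9, a gelatinase, by 0.53 (SE 0.22, adjusted p = 0.401). The list median of 0.29 passed (camera adjusted p = 0.0178; adjusted p = 0.383 with an estimated correlation) and was 0.39 within the shared number. It no longer passed without control replicate 1 (0.21), control replicate 2 (0.17) or null replicate 3 (0.25), nor over genes brighter than the median (0.09), and it was 0.60 without control replicate 3 and 0.17 without null replicate 1. Per array, the median was 0.35, -0.16 and 0.45 in null replicates 1 to 3 against -0.16, -0.22 and 0.46 in the controls.

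The list of genes that make, sense or break down leukotrienes and prostaglandins, the lipid mediators of allergic inflammation, held the most changed genes by count. Its share was below that of the eosinophil list, where 3 of 9 rose. Of the 21 lipid mediator genes 5 rose over all genes, 8 rose when adjusted over the list alone, and none fell. The list median was 0.14 and the mean 0.59 (camera adjusted p = 2.55e-04; adjusted p = 0.211 with an estimated correlation; fry adjusted p = 0.0158). Alox5, which begins leukotriene synthesis, rose 2.53-fold (log2 change 1.34, SE 0.19), its activating protein Alox5ap rose 2.47-fold (1.31, SE 0.18), and Ltc4s, the leukotriene C4 synthase, rose 2.68-fold (1.42, SE 0.18). Ptgds, a prostaglandin D synthase, went from 8.44 ± 0.20 to 10.15 ± 0.12 (log2, SD, n = 3 each; 1.71, SE 0.14, adjusted p = 0.019). Pla2g4c, a phospholipase dim in controls (5.68), rose by 2.01 (SE 0.29, adjusted p = 0.0499), or by 1.08 with the mean of its probe sets. Alox15, which acts on arachidonic acid at another position, differed by 3.33 (SE 0.62, adjusted p = 0.0909). The list median was 0.37 within the shared number. Over genes brighter than the median it was -0.09 and did not pass; it was 0.27, 0.22 and 0.08 without control replicate 3, null replicate 1 and null replicate 2, and 0.22 with the title number as a random block.

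Genes of acute inflammation shifted upward as a list, with a median of 0.84 (camera adjusted p = 7.41e-09; adjusted p = 0.283 with an estimated correlation) and of 1.07 within the shared number. Il1rn, the antagonist of the interleukin-1 receptor, went from 9.12 ± 0.26 to 11.26 ± 0.58 (log2, SD, n = 3 each), 4.41-fold (log2 change 2.14, SE 0.30, adjusted p = 0.0499). It was the only one of 28 members to pass over all genes, and 7 rose when adjusted over the list alone. Lcn2, an iron-binding defence protein, differed by 1.13 (SE 0.17, adjusted p = 0.0599), and Saa3, an acute-phase protein, by 2.37 (SE 0.52, adjusted p = 0.128).

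Genes of Th1 cells and the interferon gamma response shifted upward as a list, with a median of 0.59 (camera adjusted p = 1.27e-04; adjusted p = 0.383 with an estimated correlation). Of the 25 genes none passed over all genes or adjusted over the list alone; the immunoproteasome subunits Psmb8 and Psmb9 differed by 1.00 (SE 0.23, adjusted p = 0.144) and 1.03 (SE 0.26, adjusted p = 0.168). The median per array against the control mean was -0.19 in null replicate 1, 1.07 in replicate 2 and 1.06 in replicate 3. The list median was 0.24 within the shared number, 0.32 with that number as a random block, 0.93 without control replicate 2, 0.33 without control replicate 3, 1.19 without null replicate 1 and 1.03 with array weights. The 19 genes of the type I interferon response had a median of 0.65 (camera adjusted p = 0.0121; adjusted p = 0.573 with an estimated correlation) that rests on single arrays: it was -0.10 (adjusted p = 0.644) without null replicate 3 and 0.35 (adjusted p = 0.17) without control replicate 1. It was 1.27 without null replicate 1, 1.05 without control replicate 3, 1.31 with array weights and 1.45 within the shared number. None of the 19 passed over all genes or adjusted over the list alone, and Oas3 and Oas1a, antiviral enzymes, differed by 2.07 (SE 0.95, adjusted p = 0.448) and 1.85 (SE 0.86, adjusted p = 0.454).

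Genes of airway club cells, the secretory cells of the conducting airways, shifted downward as a list, with a median of -0.42 (camera adjusted p = 2.15e-07; adjusted p = 0.222 with an estimated correlation; fry adjusted p = 0.0361) and of -0.29 within the shared number. Gsta3 went from 10.86 ± 0.16 to 9.66 ± 0.27 (log2, SD, n = 3 each; log2 change -1.20, adjusted p = 0.0499) and was the only one of 18 members to pass over all genes, while 7 fell when adjusted over the list alone. The tight-junction gene Cldn10 differed by -0.85 (SE 0.13, adjusted p = 0.0605) and Cyp2f2, a cytochrome P450, by -0.51 (SE 0.13, adjusted p = 0.165). Scgb1a1, the main secretory protein of these cells, differed by -0.07 (SE 0.10) at a signal of 14.40 in controls, close to the top of the arrays' range, where differences can be compressed. Ciliated cell genes had a median of -0.31 (camera adjusted p = 0.00102; adjusted p = 0.383 with an estimated correlation), and none of their 21 members passed over all genes or adjusted over the list alone. The median was 0.03 within the shared number, and the list did not pass without control replicate 1 (-0.16, adjusted p = 0.0721) or over genes brighter than the median (-0.34, adjusted p = 0.16); it was -0.19 without null replicate 1 and -0.15 with the title number as a random block. Per array, the null medians (-0.19, -0.23 and -0.16) all lay within the control range of -0.25 to 0.30. Dnaic1, a dynein chain listed under another symbol, differed by -0.59 (SE 0.21, adjusted p = 0.314) and Ccdc113 by -0.54 (SE 0.20, adjusted p = 0.343).

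Of the alveolar epithelium, genes of type II cells and surfactant lipids shifted upward, with a median of 0.15 (camera adjusted p = 0.00364; adjusted p = 0.383 with an estimated correlation) and of 0.20 within the shared number. None of 24 members passed over all genes and 3 rose when adjusted over the list alone. Sftpd, a surfactant collectin, read 13.31 ± 0.13 in controls and 13.99 ± 0.04 in null lungs (log2, SD, n = 3 each; 0.68, SE 0.11, adjusted p = 0.0719), and Fasn, the fatty acid synthase, differed by 0.59 (SE 0.13, adjusted p = 0.119). Sftpc read 14.40 and 14.38 in the 2 groups, again close to the top of the range. The type I list had a median of -0.18 (camera adjusted p = 0.00186; adjusted p = 0.383 with an estimated correlation) and of -0.26 within the shared number. None of 18 members passed over all genes and 1 fell when adjusted over the list alone, Igfbp2, a binding protein of insulin-like growth factors (-2.18, SE 0.45, adjusted p = 0.109). The 22 lung epithelial transcription factors did not pass (median 0.01, camera adjusted p = 0.627; adjusted p = 0.819 with an estimated correlation), with -0.02 within the shared number. None passed over all genes, and Elf3 (0.82, SE 0.17, adjusted p = 0.106) and Foxa3 rose when adjusted over the list alone.

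Genes of developing thymocytes, listed as markers of neighbouring tissue, had the highest median of all lists, 1.72 (camera adjusted p = 4.42e-05; adjusted p = 0.38 with an estimated correlation). Of 11 members 2 rose over all genes; adjusted over the list alone 5 rose and 1 fell. Dntt went from 6.80 ± 1.03 to 10.88 ± 0.64 (log2, SD, n = 3 each), 16.9-fold, and its other probe sets gave 4.34 and 3.53. Arpp21, expressed in thymocytes and dim in controls (4.31), rose by 2.00 (SE 0.18, adjusted p = 0.0198), or by 1.30 (adjusted p = 0.0708) with the mean of its probe sets. Rag1, which cuts antigen receptor genes, differed by 4.24 (SE 0.62, adjusted p = 0.0534). The list median was 0.91 within the shared number, 1.05 without control replicate 3 and 0.98 (adjusted p = 0.498) over genes brighter than the median. Per array, the list median against the control mean was 1.55, 2.54 and 1.02 in null replicates 1 to 3, and 0.04, 0.25 and -0.76 in the controls.

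T cell genes, which share 3 members with the thymocyte list, shifted upward with a median of 0.85 (camera adjusted p = 1.15e-05; adjusted p = 0.383 with an estimated correlation). None of 18 passed over all genes or adjusted over the list alone; Cd8a, a T cell co-receptor, differed by 2.27 (SE 0.76, adjusted p = 0.297) and Foxp3, the factor of regulatory T cells, by 0.40 (SE 0.13, adjusted p = 0.281). Their median was 0.24 within the shared number, 0.56 with that number as a random block and 0.40 without control replicate 3. Per array, the T cell median was 0.63, 1.47 and 0.50 in null replicates 1 to 3 against 0.13, 0.68 and -0.85 in the controls. All 24 cell cycle genes had a positive change, with a median of 0.79 (camera adjusted p = 1.41e-08; adjusted p = 0.383 with an estimated correlation), 0.44 within the shared number and 0.45 without control replicate 3. None passed over all genes and 1, the thymidine kinase Tk1 (1.15, SE 0.23, adjusted p = 0.106), rose when adjusted over the list alone. Cell cycle medians per array followed the thymocyte list: 0.75, 1.20 and 0.56 in null replicates 1 to 3 and 0.27, 0.35 and -0.74 in the controls. With the thymocyte list's value as a term in the model, the group difference of the cell cycle list was -0.35 (SE 0.42) in place of 0.87. That term itself separates the groups, so this value does not decide whether the cell cycle rise comes from thymocytes.

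Among B cell and plasma cell genes, 1 of 16 rose over all genes and 2 when adjusted over the list alone. Ighm, the heavy chain of immunoglobulin M, went from 9.28 ± 0.34 to 11.79 ± 0.66 (log2, SD, n = 3 each; 2.51, SE 0.35, adjusted p = 0.0484), but its 10 other probe sets gave 0.04 to 1.35 and their mean gave 0.54 (adjusted p = 0.135). Jchain, which joins secreted antibodies, differed by 3.52 (SE 0.88, adjusted p = 0.169). The median was 0.44 (camera adjusted p = 4.10e-04; adjusted p = 0.383 with an estimated correlation), 0.24 within the shared number, 0.19 without control replicate 3, 0.24 without null replicate 1 and 0.15 with array weights. The 12 natural killer cell genes did not pass (median 0.91, camera adjusted p = 0.0639; adjusted p = 0.545 with an estimated correlation). Their controls ran from -1.25 to 1.43 per array, and the median was -0.07 within the shared number, 0.16 without control replicate 3 and 0.48 without null replicate 2. The list passed without control replicate 2 (1.31, adjusted p = 2.53e-04), without null replicate 1 (1.46, adjusted p = 0.00183) and with array weights (1.13, adjusted p = 0.0052). With trend and robust settings (adjusted p = 0.0489) and with the mean of a gene's probe sets (0.84, adjusted p = 0.0238) it passed as well. None of the 12 passed over all genes or adjusted over the list alone, and Ncr1, an activating receptor, differed by 1.09 (SE 0.52, adjusted p = 0.471).

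**Figure D3:**
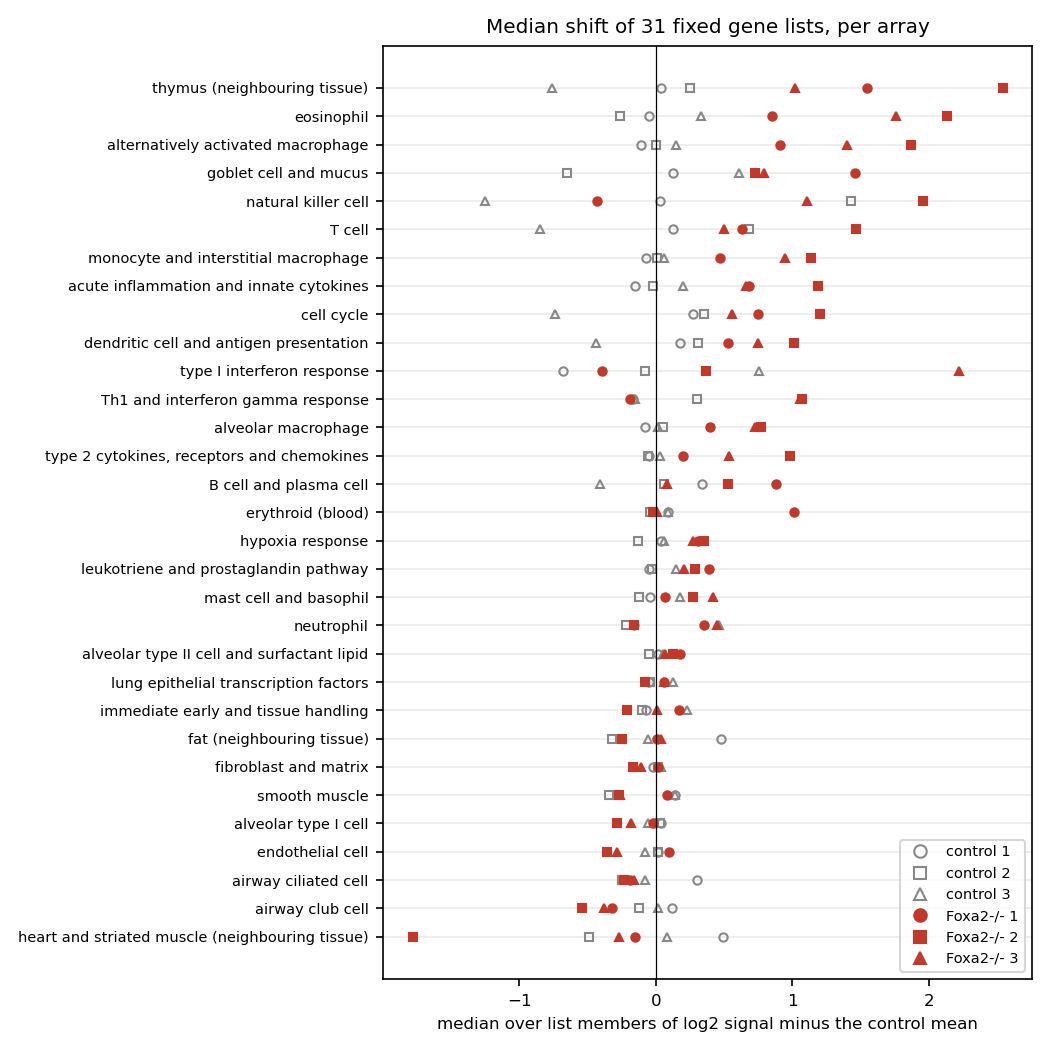
Median over list members of log2 signal minus the control mean, for each of the 31 fixed lists and each array (open grey symbols for controls, filled red ones for Foxa2-/-). Null arrays run from 1.02 to 2.54 in the thymus list, from 0.85 to 2.13 in the eosinophil list, from 0.91 to 1.87 in the alternatively activated macrophage list and from -0.39 to 2.22 in the type I interferon list, while control arrays spread from -1.25 to 1.43 in the natural killer cell list.

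Of the endothelial, fibroblast and smooth muscle lists, only the endothelial one passed. Endothelial genes had a median of -0.19 (camera adjusted p = 0.00301; adjusted p = 0.383 with an estimated correlation), -0.34 within the shared number, -0.32 without null replicate 1 and -0.29 with array weights. Without null replicate 2 it was -0.05 and did not pass (adjusted p = 0.0866). None of the 17 passed over all genes or adjusted over the list alone, among them the angiopoietin receptor Tek (-0.30, SE 0.11, adjusted p = 0.333). The 21 fibroblast and matrix genes did not pass (median -0.11, camera adjusted p = 0.0527; adjusted p = 0.311 with an estimated correlation), although fry gave an adjusted p of 0.0487; the median within the shared number was -0.16. Its median was -0.06 without control replicate 1 and -0.07 without control replicate 2, null replicate 2 or null replicate 3. The list passed too with trend and robust settings (adjusted p = 0.021), array weights (0.0498) and the title number as a random block (0.0344), and without control replicate 3 (0.0426). Neither did the 12 smooth muscle genes (median -0.16, camera adjusted p = 0.123; adjusted p = 0.545 with an estimated correlation; -0.05 within the shared number). Without control replicate 2 (-0.25, adjusted p = 0.00132) and without null replicate 1 (-0.28, adjusted p = 0.0311) the smooth muscle list did pass, while without control replicates 1 and 3 its median was -0.07 and -0.08. In both lists 0 members passed over all genes and 0 adjusted over the list alone. Timp1, an inhibitor of matrix proteases in the fibroblast list, differed by 1.65 (SE 0.51, adjusted p = 0.258), and Tagln, a smooth muscle protein, by -0.30 (SE 0.19, adjusted p = 0.586).

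Markers of other neighbouring tissue were also read. Heart and striated muscle genes shifted downward with a median of -0.67 (camera adjusted p = 2.55e-04; adjusted p = 0.383 with an estimated correlation), and none of the 14 had a positive change. None passed over all genes; 1 fell when adjusted over the list alone, Myh7, a myosin heavy chain (-2.48, SE 0.41, adjusted p = 0.0658). The median was -0.40 within the shared number, -0.28 without null replicate 2, -0.39 without control replicate 1 and -1.01 without null replicate 1. Per array, it was -0.15, -1.78 and -0.27 in null replicates 1 to 3 against -0.49 to 0.49 in the controls. Fat genes did not pass (median -0.12 over 10 genes, camera adjusted p = 0.942; adjusted p = 0.971 with an estimated correlation; 0.15 within the shared number), and camera's direction for them was upward, opposite to their median. The 10 erythroid genes had a median of 0.30 (camera adjusted p = 0.0569; adjusted p = 0.545 with an estimated correlation; 0.06 within the shared number), with 1.01 in null replicate 1 against -0.02 and 0.01 in the other null lungs. That list passed without null replicate 2 (0.53, adjusted p = 0.00704), without null replicate 3 (0.40, adjusted p = 0.026), with trend and robust settings (adjusted p = 0.0492) and with the mean of a gene's probe sets (0.35, adjusted p = 0.0383). Its median was -0.01 without null replicate 1 and 0.04 with array weights. No fat or erythroid gene passed over all genes or adjusted over the list alone; Adipoq, a fat cell hormone, differed by -1.50 (SE 0.92, adjusted p = 0.576).

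Hypoxia response genes shifted upward with a median of 0.31 (camera adjusted p = 0.00188; adjusted p = 0.279 with an estimated correlation; fry adjusted p = 0.0379), 0.28 within the shared number and 0.20 over genes brighter than the median. Of 16 members 1 rose over all genes and 2 when adjusted over the list alone. The riser was Mt1, a metal-binding metallothionein that also answers to other stresses, which went from 11.72 ± 0.20 to 12.88 ± 0.11 (log2, SD, n = 3 each; 1.16, SE 0.14, adjusted p = 0.036; 1.79 with the mean of its probe sets). The glycolytic enzyme Ldha differed by 0.52 (SE 0.12, adjusted p = 0.144). Immediate early genes, which respond to tissue handling, did not pass (median -0.02, mean 0.08, camera adjusted p = 0.627; adjusted p = 0.836 with an estimated correlation; 0.01 within the shared number). None of these 18 passed over all genes or adjusted over the list alone, and Egr2 differed by 1.61 (SE 0.36, adjusted p = 0.128).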

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

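The alternatives were all planned before the data were examined, and where a value moved the cause was not tested unless it is stated. Array number limits all of them: leaving out 1 array in turn gave 0 to 249 changed genes in place of 104, 0 to 144 changed probe sets in place of 45, and a Foxa2 difference of -5.12 to -3.83 in place of -4.30, which passed only without null replicate 1. The gene lists that shifted, 24 of 31, numbered 19 to 27 without each array and under every other setting except those of the list test itself and the title number as a fixed block or restriction, where 1 control array carries each difference. With an estimated correlation 0 lists passed, and with fry 7 did (5 higher, 2 lower); the medians of the type 2 list (0.91) and of the goblet list (0.94) are then the same and only their adjusted p moved, to 0.311 and 0.328 with an estimated correlation and to 0.072 and 0.0938 with fry. An adjusted p under 0.1 gave 320 genes and 232 probe sets. Cyclic loess gave 48 genes (36 higher, 12 lower) and 6 probe sets, of which 2 were higher and 4 lower, where the reported split was 36 and 9; it moved the median gene by 0.01 and median centring by 0.023. Genes brighter than the median gave 52 calls among fewer genes tested. Trend and robust settings gave 72 probe sets and let Foxa2 pass (-4.30, adjusted p = 0.044). Array weights, which weigh null replicate 1 at 0.262, gave 534 genes and 564 probe sets, with Foxa2 at -4.94 (adjusted p = 0.00535). The title number as a random block (consensus correlation 0.603 over genes and 0.575 over probe sets, which comes only from the 3 samples that share a number) gave 399 genes and 279 probe sets, with Foxa2 at -4.64 (adjusted p = 0.0177). As a fixed block, or with only the 3 samples that share it, which is the same fit and rests on 1 control, it gave 0 genes and 0 probe sets (2121 and 4507 at an unadjusted p under 0.05). Over its alternatives the adjusted p of Foxa2 ran from 0.00227 to 0.214; it is not among the genes brighter than the median, so that setting gave no value.

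Direction turned only for lists or genes with small or uneven differences. The lung epithelial transcription factors, at 0.01 as reported, gave -0.10 over genes brighter than the median, -0.03 with array weights, -0.02 with the title number as a fixed or random block or a restriction, and -0.06 to 0.04 with 1 array left out. The fat list, whose reported median was -0.12 and whose camera direction was upward, changed the sign of its median to 0.20 over genes brighter than the median, 0.15 with the fixed block or restriction and 0.06 with the random block; with 1 array left out it ran from -0.27 to 0.17. The immediate early list gave 0.00 after median centring, 0.01 with the fixed block or restriction, 0.05 with the random block, and -0.15 to 0.12 with 1 array left out. Over genes brighter than the median the leukotriene list was -0.09 and the mast cell list -0.23. Within the shared title number the ciliated list was 0.03, the natural killer list -0.07 and Adipoq 0.12. With 1 array left out the erythroid list ran from -0.01 to 0.53 and the type I interferon list from -0.10 to 1.27. Of 1085 comparisons of single named genes with an alternative, 792 kept direction and side of the threshold, 267 no longer passed, 24 passed newly and 2 turned. Of 522 for the lists other than the type 2 and goblet lists, the numbers were 423, 52, 18 and 29. Results that did not pass as reported count as kept when they again do not pass. The 267 and the 52 come only from results that had passed, so the numbers kept do not show how often a call held. The fixed block and the restriction, which are the same fit, are both counted, and the 2 that turned are Adipoq there. The replicate numbers pair no samples, and differences of dim probe sets near the floor can be compressed.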

Other observations

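The genes in this paragraph were chosen after their values were seen. Both parts of an epithelial enzyme that makes hydrogen peroxide rose in the null lungs, the oxidase Duox1 by 1.87 (SE 0.23, adjusted p = 0.0382) and its maturation factor Duoxa1 by 3.15 (SE 0.22, adjusted p = 0.0152). Slc5a1, a sodium-driven glucose transporter, rose by 2.78 (SE 0.29), and Rragd, a GTPase of nutrient sensing at the lysosome, by 2.69 (SE 0.25). Tnfsf9, the ligand of Tnfrsf9, rose by 1.96 (SE 0.22) beside its receptor. The coagulation factors F7 and F10 rose by 1.86 (SE 0.18) and 1.72 (SE 0.18). Further lipid mediator genes outside the fixed list rose, Tbxas1, the thromboxane synthase, by 1.57 (adjusted p = 0.0406) and Pla2g5, a secreted phospholipase (adjusted p = 0.0484). Control means of Duox1 and Pla2g5 (5.08 and 5.57) are dim, so the size of their changes is uncertain. Csf2rb, a receptor chain for interleukin-3, interleukin-5 and GM-CSF, and Csf2rb2, one for interleukin-3, rose by 1.54 (SE 0.15) and 1.98 (SE 0.17). Spi1, the myeloid transcription factor PU.1, rose by 1.10 (SE 0.15), the immune receptor adaptors Tyrobp and Fcer1g by 1.01 (SE 0.13) and 1.03 (SE 0.14), and the receptor Fcgr3 by 1.31 (SE 0.16). All 3 null arrays lay above all 3 controls for each of these genes, and like the other calls they end when control replicate 1, control replicate 2 or null replicate 3 is left out.

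Among the tests that follow, 6 were chosen after the result they measure was seen: the 2 with the thymocyte list as a model term, the 2 on a batch that follows the title number, and the 2 on RNA of null animals in control replicate 3. So was the comparison of each null array held out under 1 rule. Of the tests on control replicate 3, a first test, written before, used the 18 genes that fell; it was dropped because they had been called with that control in the fit. The model with the thymocyte list as a term was run on 6 lists, and the 2 weighed below were picked from them. In the other 4 the group difference went from 0.88 to -0.81 (SE 0.51) for T cells, from 1.38 to 1.00 (SE 0.61) for alternatively activated macrophages, from 0.64 to 0.56 (SE 0.27) for alveolar macrophages and from 0.96 to 1.76 (SE 0.84) for the goblet list. Each such fit has 6 arrays and 3 coefficients, and the thymocyte list had been seen to move with the cell cycle list.

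The median of the thymocyte list was higher in every null array than in any control. Of its 11 members, 7 lay above all controls in every null array and 1 lay below. Since the label of whole lung does not exclude pieces of thymus, 19 further thymocyte genes and 7 thymic epithelial genes were read. The 19 had a median of 0.54, and 3 of them (15.8%) lay above all controls, as did 1972 of all 18193 genes. Several of the 19 were already bright in control lungs, among them Cd24a (13.60), Ets1 (12.91) and Tcf12 (12.30). A small share of thymus RNA would hardly raise those, so this count cannot weigh against thymus tissue. Of the 7 (median 0.71) 3 lay above all controls, Psmb11, Aire and Tbata (7.58, 9.59 and 7.67 in null replicates 1 to 3 against 5.37 to 6.66 in controls). Prss16 read 5.60, 9.16 and 6.90 against 5.48 to 5.73, and Ccl25 read 8.41, 10.60 and 9.24 against 8.51 to 8.67. Thymus tissue may therefore be present in null lungs, but null replicate 1, high in Dntt (11.03), goes with it in Psmb11, Aire and Tbata and not in Prss16 and Ccl25. Foxn1 (5.94, 5.76 and 5.63 against 5.79 to 5.90) and Pax1 (6.06, 6.93 and 6.03 against 5.43 to 6.04) overlapped the controls. Psmb11 was dim in controls (4.96) and in null replicate 3 (5.27), and Aire differed by only 0.32. These values do not decide. Precursor B cells, which also make Dntt, cannot be told apart either: 8 of their genes had a median of -0.02, with an interval from resampling the genes of -0.15 to 0.59. With the thymocyte list as a model term, the group difference of the cell cycle list went from 0.87 to -0.35 (SE 0.42, slope 0.66, SE 0.20), and that of the eosinophil list from 1.57 to 1.43 (SE 0.96); neither decides, because that term itself separates the groups. An effect of Foxa2 loss on lymphoid precursors in the lung was not tested and stays open.

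Null replicate 1 stands apart from the other null lungs. Degraded RNA is argued against by its 3-prime minus 5-prime difference of Actb, 0.44, which lies between 0.43 and 0.47 in the others. A smaller response is a candidate explanation, as null replicate 1 kept more Foxa2 (7.72 against 5.38 and 5.13). Over 248 genes called without it the median ratio to the others was 0.56 (interval 0.52 to 0.61). With genes picked by 1 rule for each null array held out it was 0.59 (0.56 to 0.64), against 1.21 and 0.83 for null replicates 2 and 3. Both intervals come from resampling genes within 1 array, so they hold no spread between animals. The 1 rule does not make the picking alike. Genes for null replicate 1 were picked on null replicates 2 and 3, the closest pair of arrays (r 0.9921), which share a title number. Genes particular to that number can lower the ratio of null replicate 1, so these ratios do not decide. A smaller response does not hold for every list: of the 24 that passed, null replicate 1 moved least in 13 but furthest in 4, the goblet (1.46 against 0.73 and 0.79), leukotriene (0.39 against 0.29 and 0.21), B cell (0.88 against 0.53 and 0.08) and alveolar type II lists. A batch that follows the title number cannot be told apart from this, because 0 other null arrays share its number.

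Goblet cell genes and Chil4 differed between control arrays: Clca1 read 10.95, 7.08 and 11.61, and Chil4 7.75 in control replicate 1, less in control replicate 2 and 12.47 in control replicate 3. The alternative activation list as a whole varied little between controls, with medians from -0.11 to 0.15 per array. RNA or tissue of null animals in control replicate 3 is argued against by Foxa2, at the share that Chil4 needs: it read -0.14 against the other controls (control SD 0.16), where the mildest drop, with null replicate 1 as donor at a share of 56%, would be -0.93. A set of 72 genes lower in null arrays, picked without that control, does not decide: its median there was -0.40 (SD 0.71) against -0.78 at a share of 68.9%, and controls 1 and 2 held out in the same manner gave -0.14 and -0.32. A much smaller share stays open if the Chil4 signal is compressed at its high end. A batch that follows the title number cannot be told apart, because 0 controls share a number with another control, and neither can differences between animals or litters, which were not tested: the arrays that share the number were lowest in the goblet list in both groups (-0.65 against 0.13 and 0.61, and 0.73 and 0.79 against 1.46).

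The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 104 changed genes against at most 1 in another split, and 1 split, the real one, reached that number. For probe sets the values were 45 and 1 (1 split as large), for shifted lists 24 and 21 (1 split), for the size of the type 2 list's median 0.91 and 0.61 (1 split), and for that of the goblet list 0.94 and 1.00 (2 splits). The split with 21 lists sets control replicate 1 and null replicates 2 and 3 against the rest, and the one with 1.00 sets null replicate 2 with control replicates 1 and 2.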
